A study of Macaca mulatta with 5 samples.

How the data were processed

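Total RNA from oropharyngeal tissue of 5 rhesus macaques was extracted with a column kit, copied into cDNA, transcribed in vitro into biotin-labelled cRNA and hybridised to 1-colour expression arrays, per the labels' protocols. The groups, 3 uninfected animals and 2 animals infected for 6 weeks with SIVmac251, come from the labels. Replicates were numbered in the order of deposition, so the numbers only name animals and pair none. Each sample is a different animal per the series design.

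The deposited values are probe set intensities on a linear scale, 1 column per array, as the authors made them. The background correction, summarisation and normalization behind them are not given in the sources used here. Their 2% trimmed means lay between 116 and 123 on all 5 arrays, so the arrays had been brought to a similar overall scale. The deposited table held 52865 probe sets, of which 99 control probe sets were left out, leaving 52766. No column of per-sample values was left unused.

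Genes were named through the platform's annotation, dated 2016. It gave 1 gene symbol for 24956 of the kept probe sets (14132 different symbols), several symbols for 361 and did not list 27449. Probe sets with several symbols or none were tested but not named. Symbols were checked through Entrez IDs against a RefSeq gene table of assembly T2T-MMU8v2.0, which held the IDs of 24616 probe sets, and 0 symbols needed an update. No coordinates are given, because the build behind the array design is not given in the sources used here.

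The deposited intensities were kept as scaled by the authors and turned into log2(intensity + 18.5), where the pseudocount is the 20th percentile of all values. Probe sets whose mean log2 value over the 5 arrays lay above the 40th percentile of such means (5.74) were tested, 31659 in all. Such a filter can keep probe sets that are bright in only 1 group, but it also drops some of them, and it removes those dim in both. limma 3.58.1 in R 4.3.3 was used, with lmFit and eBayes (trend = TRUE) and 3 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. As a description with no test, probe sets at least 2-fold apart with groups that did not overlap were counted. Chance gives such separation, at any fold, for 20% of probe sets on average.

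The gene lists, 29 in all, covered interferon and antigen-presentation genes, the cell types an oropharyngeal sample could hold, epithelial and glandular functions, metabolism, blood and handling stress. Of 765 list members, 566 had a probe set. A gene was represented by the probe set with the highest mean, and lists were tested on 11500 genes with camera in limma at its preset inter-gene correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move, on balance, one way, and does not compare the list with other genes.

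Named genes followed a rule: the 12 genes per direction with the smallest unadjusted p among those at least 2-fold apart without overlap (used because no named gene passed the adjusted threshold), the 4 members of each list with the smallest p, and a fixed panel (with CD4, CD8A, GZMB, PRF1, IFNG, MX1, ISG15, CXCL10, DEFB1, KRT13 and EGF). PRF1 was not listed in the annotation used here. One further panel gene and one gene chosen by the p rule are not reported here, and of the list members so chosen the text gives values for some and not for all. Genes named outside the rule are marked as chosen after their values were seen. The groups, main tests, lists, naming rule and alternatives were fixed before the data were examined. The fit with the B-cell list mean as a covariate was added afterwards, as were the tests on the cytotoxic list against other cell types, the hybridization controls, the mitochondrial probe sets and the 2-fold share of other probe sets.

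Alternatives covered quantile normalization, median centring, other pseudocounts (5th and 40th percentile), no filter or one at the 60th percentile, leaving out each animal, array weights, a variance prior without trend or robust, an adjusted p under 0.1, 1 probe set per gene, a 1.5-fold threshold, the mean of all probe sets of a gene, and the other set tests. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

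The tests were tested on simulated data for the comparison of infected with uninfected animals, over 31659 probe sets of which 200 were changed. They called 6% of probe sets changed by 1 on the log2 scale, 42% of those changed by 2, 80% by 3 and 88% by 4. The sign was right for 99.5%, and 4 unchanged probe sets were called. Of 29 simulated lists the shifted list was called and 0 others, in data simulated without correlation between genes. That list also passed with an estimated correlation (adjusted p = 0.042) and with fry (adjusted p = 0.021).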

Results

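The oropharyngeal tissue of 5 rhesus macaques (Macaca mulatta) was profiled on expression arrays, 1 array per animal. In 2 animals the tissue was taken after 6 weeks of infection with SIVmac251, a pathogenic strain of simian immunodeficiency virus, and the other 3 animals were uninfected healthy controls. The comparison asks how the oral mucosa responds to SIV infection. Each array gave intensities for 52766 probe sets after control probe sets were left out, and 31659 of them were bright enough to be tested. The median intensity per array lay between 42.0 and 52.9 arbitrary units. The number of arrays limits the precision: an exact rank test of 2 animals against 3 cannot go below p = 0.2 (two-sided). Below, intensities are means ± SD over 3 uninfected and 2 infected animals, and log2 fold changes (infected minus uninfected, ± SE) are on the log2(intensity + pseudocount) scale, which understates the change of dim genes.

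Interferon-responsive, antigen-processing and cytotoxic lymphocyte genes were higher in the infected tissue and salivary gland genes lower, as groups, in limma's camera test with its preset correlation, but none passed with an estimated correlation or with fry. Array controls also separated the infected from the uninfected animals. CD8A, the alpha chain of the CD8 co-receptor, averaged 125 ± 66.3 in the uninfected and 1073 ± 217 in the infected animals, and the T-cell-attracting chemokine CXCL9 averaged 28.5 ± 8.49 in the uninfected and 535 ± 395 in the infected animals. PIGR, which carries antibodies across glandular epithelium, averaged 99.9 ± 16.4 in the uninfected and 41.6 ± 3.81 in the infected animals. No single annotated gene passed the threshold over all probe sets tested. Of the 29 gene lists fixed before the data were examined, 14 passed with the preset correlation, 11 higher and 3 lower. None of the 14 passed with an estimated correlation (adjusted p = 0.54 to 0.55) or with fry (adjusted p = 0.19 to 0.39), and 39 list entries passed when adjusted over the list alone (IDO1 counted in both its lists). In 8 of the 14 called lists both infected animals lay outside all 3 uninfected animals, and in the other 6 the animals overlapped. Over all 29 lists 10 separated the animals in this way, where chance gives 5.8 on average, for lists that are not independent.

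**Figure D1:**
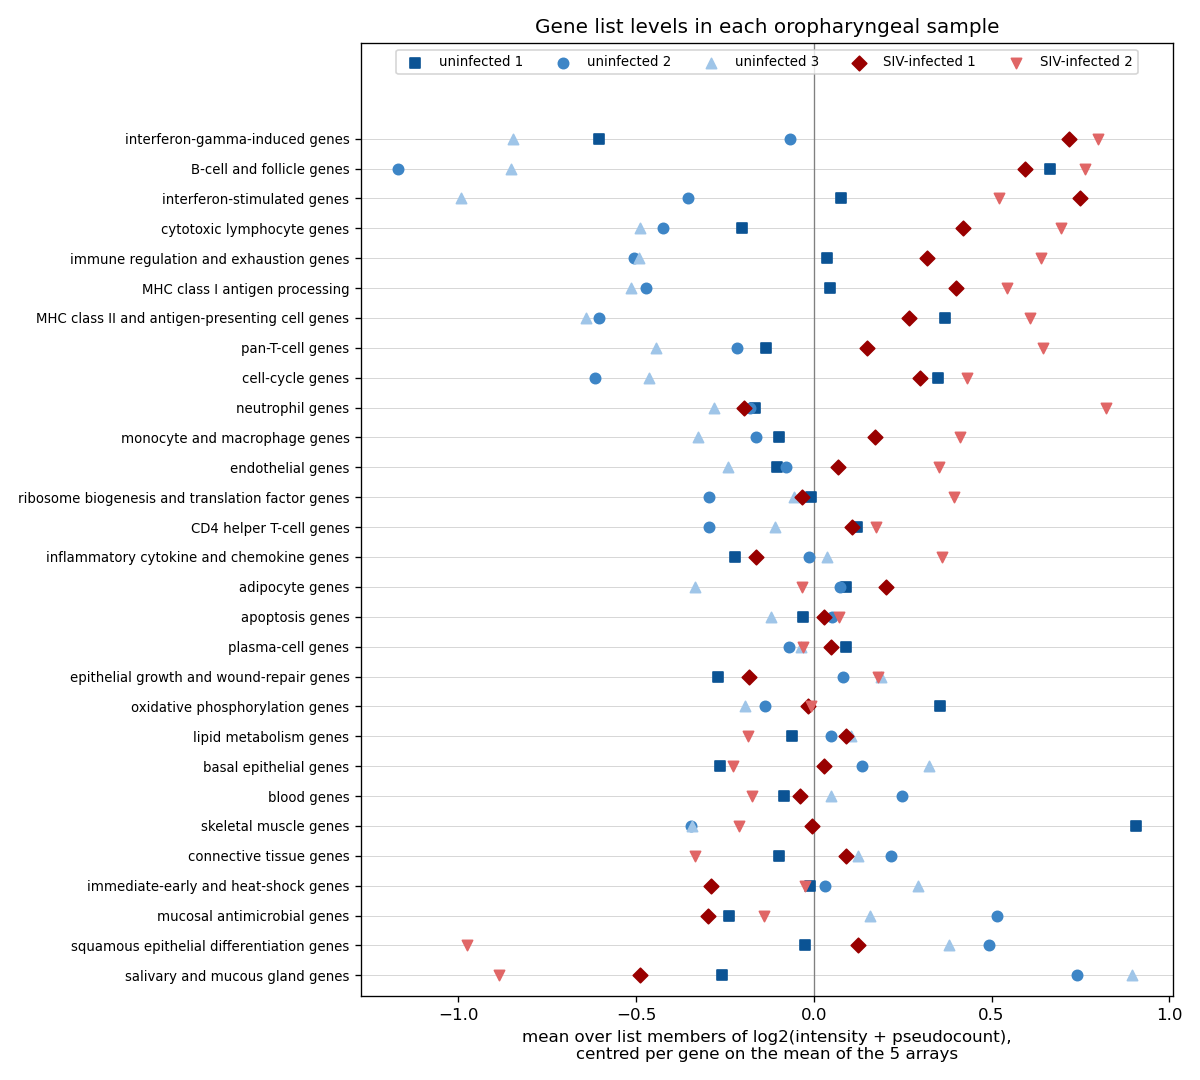
Mean level of each of the 29 gene lists in each of the 5 oropharyngeal samples. The x axis gives the mean over list members of log2(intensity + pseudocount), centred per gene on the mean of the 5 arrays, and each point is 1 animal (blue, uninfected; red, SIV-infected). Both infected animals sit above all 3 uninfected animals for the cytotoxic list (0.42 and 0.70 against -0.20, -0.43 and -0.49), while uninfected animal 1 sits between the infected animals for the B-cell list.

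Interferon-stimulated genes, which encode antiviral effectors and sensors, were higher in the infected animals for 30 of 32 tested members, with a median log2 fold change of 1.22 (limma camera adjusted p = 8.9e-10, adjusted p = 0.54 with an estimated correlation). PARP14, a mono-ADP-ribosyltransferase, averaged 122 ± 54.6 in the uninfected and 464 ± 23.6 in the infected animals (log2 fold change 1.86 ± 0.40). IFIH1, which encodes the double-stranded RNA sensor MDA5, averaged 196 ± 81.6 against 624 ± 256, and SAMD9L averaged 221 ± 105 against 627 ± 45.9. MX1, a GTPase that restricts viruses, stood at 689, 229.9 and 67.6 in the uninfected animals and at 1069 and 822 in the infected animals. ISG15, a ubiquitin-like modifier, overlapped between the groups (778 ± 506 against 1553 ± 1077). Adjusted over the list alone, 2 of the 32 members passed, PARP14 and PARP9.

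Genes induced by interferon gamma were higher for 12 of 13 tested members, with a median of 0.99 (limma camera adjusted p = 7.5e-06, adjusted p = 0.54 with an estimated correlation). They included the chemokines CXCL9 (log2 fold change 3.36 ± 0.46, limma adjusted p = 0.11 over all probe sets) and CXCL10, which averaged 178 ± 215 in the uninfected and 1181 ± 346 in the infected animals. Both are ligands of CXCR3, but CXCL11, also a CXCR3 ligand, was the 1 lower member (log2 fold change -0.40 ± 0.46). It read 434, 629 and 528 in the uninfected and 677 and 224 in the infected animals, and was chosen after its values were seen. IDO1, the tryptophan-degrading enzyme, averaged 198 ± 64.2 against 1049 ± 264, and UBD, a ubiquitin-like protein, averaged 273 ± 123 against 849 ± 178. Adjusted over the list alone, 5 of the 13 members passed. IFNG itself was too dim to be tested, at 19.6 ± 4.06 against 38.7 ± 0.720.

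Antigen processing for MHC class I was higher for 11 of 13 members, with a median of 0.83 (limma camera adjusted p = 7.4e-05, adjusted p = 0.55 with an estimated correlation), and 5 passed when adjusted over the list alone. NLRC5, the transactivator of MHC class I genes, averaged 153 ± 54.5 in the uninfected and 566 ± 6.93 in the infected animals. The immunoproteasome subunit PSMB8 averaged 361 ± 134 against 1037 ± 57.5, and the peptide transporter TAP1 averaged 353 ± 130.1 against 888 ± 14.4. MHC class II and antigen-presenting cell genes were higher for 13 of 17 members, with a median of 0.86 (limma camera adjusted p = 0.0078, adjusted p = 0.55 with an estimated correlation), and no member passed when adjusted over the list alone. Here uninfected animal 1 lay with the infected animals: its list mean was 0.37, against -0.61 and -0.64 in the other uninfected and 0.27 and 0.61 in the infected animals. The lysosomal reductase IFI30 showed this pattern, at 1408 in uninfected animal 1, 292 and 287 in the other uninfected and 1822 and 1864 in the infected animals. MAMU-DMA and MAMU-DOB were also brighter in the infected animals (641 ± 619 against 1763 ± 176 and 164 ± 178 against 543 ± 146), but MHC genes are a multigene family whose probe sets can cross-hybridise.

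Cytotoxic lymphocyte genes were higher for 19 of 24 tested members, with a median of 0.54 (limma camera adjusted p = 1.4e-06, adjusted p = 0.54 with an estimated correlation). This list had the most members past the threshold when adjusted over the list alone, 10 of 24. CD8A had a log2 fold change of 3.00 ± 0.40 (limma adjusted p = 0.11 over all probe sets). The granule protein NKG7 averaged 74.7 ± 20.3 against 458 ± 123, the chemokine CCL5 averaged 28.1 ± 7.76 against 265 ± 115, and CRTAM, a surface receptor of activated cytotoxic cells, averaged 12.4 ± 3.28 against 122 ± 51.0. The serine protease GZMB averaged 197 ± 169 in the uninfected and 966 ± 309 in the infected animals (log2 fold change 2.43 ± 0.59). The members differed from each other: GZMA had a log2 fold change of -1.06 ± 0.44, and KLRD1, a receptor subunit of natural killer cells, had 0.01 ± 0.23, both chosen after their values were seen. PRF1 was not listed in the annotation used here.

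Pan-T-cell genes were higher for 7 of 11 tested members, with a median of 0.61 (limma camera adjusted p = 0.02, adjusted p = 0.55 with an estimated correlation), and 3 passed when adjusted over the list alone. UBASH3A, a regulator of T-cell receptor signalling, averaged 26.5 ± 8.02 against 159 ± 40.6, PTPN22, a phosphatase of the same pathway, averaged 19.98 ± 8.94 against 151 ± 37.7, and TRAT1 averaged 34.2 ± 29.3 against 229 ± 118. This call was lost without infected animal 2 (limma camera adjusted p = 0.38, median -0.093), and also without uninfected animal 1. CD4, the receptor that SIV uses to enter cells, averaged 62.8 ± 14.0 in the uninfected and 51.0 ± 1.13 in the infected animals, a difference smaller than the uninfected SD. Its only probe set was dim, where the array medians were 42.0 to 52.9, so a loss or gain of CD4 could be missed. The CD4 helper T-cell list did not pass (5 of 9 members higher, median 0.35, limma camera adjusted p = 0.23), and its members went both ways. Of its 17 members with a probe set, 8 were too dim to be tested. ICOS, a co-stimulatory receptor, averaged 43.5 ± 24.5 against 126 ± 10.5. The nuclear receptor RORA averaged 209 ± 62.0 against 91.9 ± 66.7, with groups that overlapped. Immune regulation and exhaustion genes were higher for 10 of 13 members, with a median of 0.86 (limma camera adjusted p = 0.00021, adjusted p = 0.54 with an estimated correlation), and 4 passed when adjusted over the list alone. Among them the inhibitory receptor LAG3 averaged 36.7 ± 12.5 against 129.6 ± 43.9 and the ectonucleotidase ENTPD1 averaged 90.9 ± 11.1 against 179 ± 11.1.

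**Figure D2:**
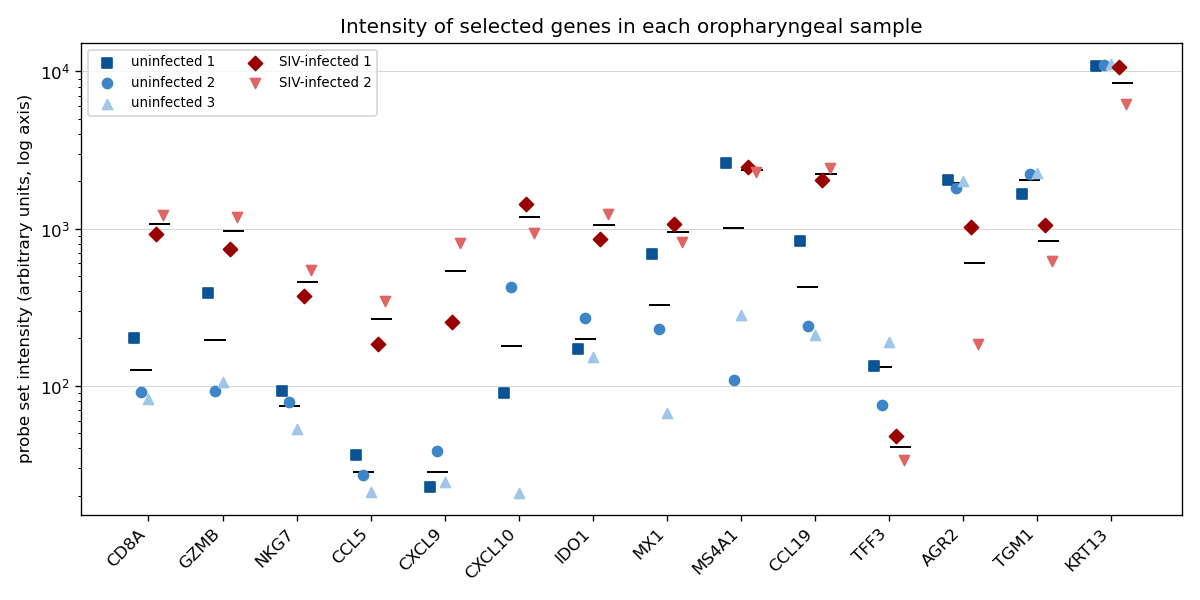
Probe set intensity, in arbitrary units on a log axis, of 14 genes in each of the 5 oropharyngeal samples. Each point is 1 animal (blue, uninfected; red, SIV-infected) and each black line is a group mean. CD8A stood at 202, 91.8 and 82.6 in the uninfected and at 919.7 and 1226 in the infected animals, while MS4A1 of uninfected animal 1 (2612) lay at the level of the infected animals (2451 and 2288).

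B-cell and follicle genes were higher for 13 of 16 members, with a median of 1.54 (limma camera adjusted p = 0.0013, adjusted p = 0.55 with an estimated correlation), and 2 passed when adjusted over the list alone. Those 2 were CCL19 and FCRL3. FCRL3 had a log2 fold change of 2.09 by its brightest probe set and 0.67 by the other tested one. CCL19, a chemokine of lymphoid stroma, averaged 428 ± 349 in the uninfected and 2234 ± 290.4 in the infected animals. CXCL13, which draws B cells into follicles, did not pass and averaged 1015 ± 963 against 3099 ± 943. By its list mean uninfected animal 1 was at the infected level, at 0.67 against 0.60 and 0.76 in the infected and -1.17 and -0.85 in the other uninfected animals. Single members differed. CCL19 read 830 in that animal, against 2029 and 2439 in the infected animals, and FCRL3 read 48.4, against 165 and 123. MS4A1, which encodes CD20 and was chosen after its values were seen, read 2612 in that animal, 109 and 284 in the other uninfected, and 2451 and 2288 in the infected animals. Cell-cycle genes followed the same animals: 18 of 20 members were higher, with a median of 0.72 (limma camera adjusted p = 5.7e-05, adjusted p = 0.55 with an estimated correlation), but uninfected animal 1 had a list mean of 0.35 and the infected animals 0.30 and 0.43. The replication factors PCNA and MCM2 averaged 675 ± 289.6 against 1190.1 ± 13.9 and 185 ± 78.0 against 328 ± 20.8. With the B-cell list mean as a covariate, chosen after seeing the data, the calls of the MHC class II, cell-cycle, squamous epithelial, mucosal antimicrobial, ribosome biogenesis and, by construction, B-cell lists were lost, and the interferon-stimulated, interferon-gamma-induced, MHC class I, cytotoxic, pan-T, immune regulation, macrophage and gland lists still passed. Plasma-cell genes did not pass (6 of 11 higher, median 0.20, limma camera adjusted p = 0.91).

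Monocyte and macrophage genes were higher for 15 of 20 members, with a median of 0.53 (limma camera adjusted p = 0.00064, adjusted p = 0.54 with an estimated correlation), and 1 passed when adjusted over the list alone. That member, MS4A4A, a tetraspan protein of macrophages, averaged 35.8 ± 2.15 in the uninfected and 139 ± 12.6 in the infected animals. CSF1R, the receptor for macrophage colony-stimulating factor, averaged 176 ± 90.3 against 427 ± 9.19, and the complement component C1QA averaged 351 ± 95.0 against 792 ± 173. The other tested probe set of C1QA had a log2 fold change of 0.11. Outside the lists, ADAMDEC1, a metalloprotease, averaged 68.6 ± 48.0 against 780.4 ± 119 and NR1H3, the liver X receptor alpha, averaged 36.2 ± 14.1 against 182 ± 15.5. MAP6D1 averaged 21.0 ± 0.746 against 96.1 ± 19.8.

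Salivary and mucous gland genes were lower in the infected animals for 20 of 22 tested members, with a median of -1.07 (limma camera adjusted p = 1.4e-05, adjusted p = 0.55 with an estimated correlation), and 2 passed when adjusted over the list alone. Those 2 were PIP and PIGR, the members with the smallest p. AGR2, a disulfide isomerase of mucus-secreting cells, averaged 1947 ± 112 in the uninfected and 604 ± 592 in the infected animals. The mucosal peptide TFF3 averaged 133 ± 57.0 against 40.9 ± 10.1. The other tested probe set of AGR2 was less changed, with a log2 fold change of -0.45. PIP, a secreted salivary protein, averaged 1768 ± 601 against 275 ± 81.5 by its brightest probe set, but its other tested probe set went the opposite way (log2 fold change 0.48). List means were -0.26, 0.74 and 0.90 in the uninfected and -0.49 and -0.89 in the infected animals, so uninfected animal 1 again lay nearest to the infected animals.

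Squamous epithelial differentiation genes were lower for 39 of 43 members, with a median of -0.73 (limma camera adjusted p = 7.5e-06, adjusted p = 0.55 with an estimated correlation), and none passed when adjusted over the list alone. TGM1, the transglutaminase that cross-links the cornified envelope, averaged 2051 ± 336 in the uninfected and 839 ± 309.5 in the infected animals, and the tight-junction protein CLDN4 averaged 621 ± 103 against 303 ± 33.1. PKP1, a desmosomal plaque protein, averaged 377 ± 84.4 against 160.2 ± 65.0. KRT13, the main keratin of non-cornified oral epithelium, stood at 10621 in infected animal 1, where the uninfected animals read 10874, 10984 and 11075, and at 6168 in infected animal 2. The list mean was low in infected animal 2 alone (-0.98, against 0.13 in infected animal 1 and -0.02 in uninfected animal 1), and without infected animal 2 the call was lost (limma camera adjusted p = 0.26), as it was with the B-cell list mean as a covariate. Basal epithelial genes did not pass (6 of 8 lower, median -0.07, limma camera adjusted p = 0.67), and their median changed sign in 4 of 16 alternative settings.

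Mucosal antimicrobial genes were lower for 13 of 16 members, with a median of -0.45 (limma camera adjusted p = 0.043, adjusted p = 0.55 with an estimated correlation), none passed when adjusted over the list alone, and the call was lost in 6 of 14 alternative settings. LCN2, a siderophore-binding protein, averaged 1108 ± 718 against 289.7 ± 167, with values of 346 in uninfected animal 1 and 408 in infected animal 2 that overlapped. The beta-defensins DEFB4A and DEFB1 averaged 247 ± 70.9 against 134 ± 40.2 and 1545 ± 203 against 1197 ± 614. Ribosome biogenesis and translation factor genes were higher for 21 of 24 members, with a median of 0.36 (limma camera adjusted p = 0.0076, adjusted p = 0.55 with an estimated correlation), yet EEF2, the elongation factor that moves the ribosome along the message, was the only member past the threshold when adjusted over the list alone and was lower (121 ± 4.44 against 49.9 ± 1.91). EIF4E, the cap-binding factor, was also lower (108 ± 32.1 against 54.3 ± 10.5), and the call was lost without infected animal 2 (limma camera adjusted p = 0.54).

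Across all 31659 tested probe sets, 3 passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, all of them lower in the infected animals and none named by the gene annotation. MmuMitochon.6.1.S1_s_at, a mitochondrial probe set by its ID, fell from 9240.1 ± 329 to 80.8 ± 30.0 (log2 fold change -6.58 ± 0.25, adjusted p = 0.00092). MmuMitochon.10.1.S1_s_at fell from 11438, 9481 and 8634 to 1331 and 1369.8 (limma adjusted p = 0.013), and MmugDNA.39778.1.S1_at fell from 143, 138 and 130.3 to 3.89 and 7.24 (limma adjusted p = 0.025). At an unadjusted p under 0.05 limma gave 5024 probe sets, 2219 higher and 2805 lower, where 1583 are expected by chance. Groups did not overlap for 38.7% of tested probe sets, where chance gives 20% on average over divisions of the arrays. Probe sets vary together, so a single division can lie far from these chance values. Uninfected animals 2 and 3 against the rest gave 2377 probe sets at least 2-fold apart without overlap. For infected against uninfected animals there were 1847 such probe sets, 864 higher and 983 lower. This split depended on the scaling: it was 1008 higher and 851 lower after quantile normalization and 1282 higher and 641 lower after median centring, as the median log2 fold change of all tested probe sets was -0.08 as deposited and 0.05 after median centring. Leaving out uninfected animal 1 raised the count past the adjusted threshold from 3 to 416 (319 higher, 97 lower), and leaving out uninfected animal 2 brought it to 0.

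Among genes at least 2-fold lower without overlap, those with the smallest p included IL36A, an epithelial cytokine of the interleukin-1 family, which averaged 1603 ± 701 in the uninfected and 218 ± 84.99 in the infected animals (log2 fold change -2.74 ± 0.42, limma adjusted p = 0.13). The homeobox factor PITX1 averaged 2553 ± 375 against 612 ± 115, and both its tested probe sets were lower. CEP295, a centriole protein, averaged 207 ± 52.3 against 21.9 ± 4.05. PROSER2 averaged 189 ± 72.6 against 24.4 ± 7.48. PCED1A averaged 723 ± 181 against 135 ± 28.6, and the splicing-related gene RBM25 averaged 172 ± 15.4 against 44.5 ± 15.04. For 4 more the brightest probe set was lower but another tested probe set of the gene was near 0 or higher: DAAM1 (777 ± 179.7 against 84.0 ± 23.0, other log2 fold change -0.02), SRRM2 (658 ± 141 against 62.0 ± 32.9, -0.06), the carnitine transporter SLC22A5 (319 ± 52.0 against 66.7 ± 13.1, 0.08) and PECAM1, an endothelial adhesion protein (911 ± 53.4 against 267 ± 15.3, highest 0.85).

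The 27 hybridization control probe sets, which read RNA added at the bench and not the tissue, were all dimmer in both infected arrays than in any uninfected array, by a median of 40.1%. Several of them read the same added RNA, so they are not 27 independent readings. Their geometric mean was 2032, 1509 and 1581 in the uninfected and 1045 and 1197 in the infected arrays. Chance separates a single reading of 2 against 3 arrays in 20% of cases. No label names a hybridization batch, and what dimmed the controls was not tested. A technical difference between the arrays of the groups therefore cannot be told apart from infection, and no value free of it can be given for any result above. Uninfected animal 1 stood apart from the other controls in muscle genes too, with a skeletal muscle list mean of 0.91 against -0.35 and -0.34, and its array correlated across probe sets at r = 0.86 and 0.90 with uninfected animals 2 and 3 and at r = 0.89 and 0.90 with infected animals 1 and 2. The source label of that animal reads oropharynx tissue where the other labels read oropharynx, and whether its sampling site differed is not given in the sources used here, which bears on every uninfected mean above.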

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

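The comparison with other sequence records below was planned before its result was seen. Among probe sets outside the gene annotation, 9 carry the name of 1 sequence record with numbered coding sequences, in the form this array uses for records read here as viral. No table used here names the record or its genes, and that reading rests on the form of the IDs.

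A signal in probe sets that the gene comparisons do not use stood above the control animals for 3 of these 9. AY588945.CDS7.S1_s_at averaged 138 in the infected animals (71.2 and 205), against a highest uninfected value of 53.6. AY588945.CDS8.S1_at averaged 69.3 (48.7 and 90.0 in the infected animals), against 20.5. AY588945.CDS9.S1_s_at averaged 114 (90.7 and 137), against 10.7. The other 6 probe sets of the record overlapped or were not higher, and only the first of the 3 was bright enough to pass the filter. Against a general rise of such probe sets stands the rest of the class: 0% (0 of 674) of the probe sets of other records read as viral reached the lowest log2 fold change of the 3 (1.24 ± 0.40) without overlap, and their median was -0.09. Higher without overlap at any size were 48 of the 674, so separation alone does not single out the 3. Transcripts of the infecting virus in the tissue may be the source, as the design would allow. The hybridization controls were dimmer in the infected arrays. No test linked their dimming to the level of other probe sets, so its direction does not bear on a technical source of this signal. A technical difference limited to these probe sets and cross-hybridisation to macaque transcripts were not tested.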

How the results depend on the processing

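The fit with the B-cell list mean as a covariate was chosen after seeing the data, and the other alternatives were planned. The count of probe sets past limma's adjusted threshold, 3 in the main setting, was the least stable value. Leaving out 1 animal gave 0 to 416: 416 without uninfected animal 1, 0 without uninfected animal 2, 1 without uninfected animal 3, 56 without infected animal 1 and 107 without infected animal 2. With 1 infected animal left, it is assumed to vary like the uninfected animals. Array weights gave 5792, in a fit that weighted uninfected animal 3 by 6.71 and uninfected animal 1 by 0.31. A variance prior without trend gave 1, an adjusted p under 0.1 gave 28 by its construction, 1 probe set per gene gave 0, since the 3 have no gene symbol, and the B-cell covariate gave 0. The 1847 probe sets at least 2-fold apart without overlap became 1849 to 3603 when 1 animal was left out (3551 without uninfected animal 1, 3603 without infected animal 1), where fewer animals separate more often by chance, and 5672 at a 1.5-fold threshold. The 14 called lists became 0 with an estimated correlation and 0 with fry, 12 to 15 without 1 animal, and 10 with the B-cell covariate, which left 8 of the 14. The other causes were not tested.

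The interferon-stimulated, interferon-gamma-induced, MHC class I, cytotoxic, macrophage, immune regulation and gland lists passed in all 14 settings other than the set tests, with medians of 0.63 to 1.60, 0.93 to 1.42, 0.39 to 1.08, 0.30 to 0.79, 0.46 to 0.76, 0.42 to 1.01 and -1.67 to -0.69. Pan-T-cell genes lost their call at the 60th percentile filter, without uninfected animal 1 and without infected animal 2, where the median turned to -0.093 (its range over the fits without 1 animal was -0.093 to 1.06). Squamous genes lost it without infected animal 2 and with the covariate, ribosome genes in 3 settings, mucosal antimicrobial genes in 6, and MHC class II and cell-cycle genes with the covariate. Their medians over the 14 settings were -1.28 to -0.10 for squamous, 0.13 to 0.57 for ribosome and -0.57 to -0.16 for mucosal antimicrobial genes. For MHC class II genes they were 0.08 to 1.16, and for cell-cycle genes 0.06 to 1.06. Medians turned to -0.14 for B-cell genes with their own mean as a covariate, by construction, and to -0.36 for skeletal muscle genes in that fit, which then passed. Over all lists and settings 408 values stayed on their side of the threshold, 43 lost the call, 10 gained it and 3 reversed, and for named genes 2112, 10, 155 and 0. Of the 408, 34 medians of lists without a call changed sign, as did 5 of the 2112. Of the 155 gained, most came from array weights and from leaving out uninfected animal 1. No paired analysis was possible because the labels give the animals no shared numbers. Probe sets near the pseudocount of 18.5 have compressed fold changes, so signal over background limits what can be seen for dim genes such as IFNG.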

Other observations

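Of the tests below, the B-cell covariate, the cytotoxic list against other cell types, the hybridization controls, the mitochondrial probe sets and the 2-fold share of other probe sets were chosen after the results were seen. Several lists that missed the threshold held members of interest. Endothelial genes were higher for 12 of 17 members (median 0.34, limma camera adjusted p = 0.061), short of the threshold, with both infected animals above all uninfected animals. SELE, which tethers leukocytes to inflamed vessels, averaged 23.1 ± 12.7 against 117 ± 82.2, and the endothelial cadherin CDH5 averaged 142 ± 31.6 against 282 ± 74.9 by its brightest probe set, with the other tested probe set at a log2 fold change of -0.15. Inflammatory cytokine and chemokine genes did not pass as a list (10 of 19 higher, median 0.10, limma camera adjusted p = 0.57). Within it the monocyte chemokine CCL2 averaged 98.7 ± 42.9 against 403 ± 310.1 and IL15, a growth factor of CD8 T cells and natural killer cells, averaged 54.7 ± 8.37 against 102 ± 26.9. Neutrophil genes did not pass (8 of 11 higher, median 0.40, limma camera adjusted p = 0.3) and were high in infected animal 2 alone, with a list mean of 0.82 against -0.20 in infected animal 1. In the apoptosis list (9 of 18 higher, median -0.01, adjusted p = 0.59 in limma's camera, with a median that changed sign in 7 of 16 alternative settings), the death receptor FAS averaged 106 ± 22.1 against 227 ± 40.7.

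Epithelial growth and wound-repair genes did not pass (17 of 32 higher, median 0.03, limma camera adjusted p = 0.91), and its members went both ways: EGFR, the receptor for epidermal growth factor, averaged 176 ± 92.3 against 34.2 ± 21.7 and ERBB2 684 ± 128 against 374 ± 224, while the metalloprotease MMP9 averaged 252 ± 203 against 816 ± 344 and the receptor TGFBR1 306 ± 44.1 against 509 ± 23.5. The other tested probe set of TGFBR1 had a log2 fold change of 0.03. EGF, a ligand of EGFR, overlapped between the groups (163 ± 49.5 against 96.3 ± 28.6). Immediate-early and heat-shock genes were higher for 5 of 15 members, with a median of -0.26 (limma camera adjusted p = 0.13). Both infected animals lay below all uninfected animals, with list means of -0.29 and -0.02 against -0.01, 0.03 and 0.29. ZFP36, which speeds the decay of cytokine messages, averaged 144 ± 56.6 against 23.0 ± 3.84, while the transcription factor EGR2 averaged 43.5 ± 19.5 against 115 ± 57.8. The remaining lists did not pass limma's camera test: connective tissue genes had a median of -0.24 (adjusted p = 0.48), skeletal muscle 0.01 (1.0), adipocyte 0.33 (0.37), blood -0.26 (0.3), oxidative phosphorylation -0.04 (0.92) and lipid metabolism -0.04 (0.91). Over the lists of these 2 paragraphs PECAM1, IL36A, ZFP36 and TTN passed when adjusted over the list alone, all lower. The median of oxidative phosphorylation genes changed sign in 5 of 16 alternative settings and that of lipid metabolism genes in 4. Median and mean differed in sign for skeletal muscle, whose mean was -0.18, and TTN, the giant sarcomere protein, averaged 581 ± 425 against 49.8 ± 45.5 with 1062 in uninfected animal 1.

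Cytotoxic lymphocyte genes were higher in the infected animals, and uninfected animal 1 had a B-cell list mean at the infected level. The connective tissue, skeletal muscle, endothelial, adipocyte and blood lists were not raised as far as the cytotoxic list. A smaller share of epithelium that raises the genes of every other cell type alike would raise all of them equally. The comparison was chosen after their values were seen, so it is a description and not a test. B-cell and macrophage genes were also higher (mean log2 fold changes 1.13 and 0.49) but were not among these 5 lists. A shared rise of immune cell types is not addressed. Per animal, the cytotoxic list mean minus the mean of these 5 list means was 0.94 higher in the infected animals (SE over animals 0.16), at 0.36 and 0.78 against -0.34, -0.45 and -0.34. Against each of the 5 lists alone both infected animals also lay above all uninfected animals, by the least on average for endothelial genes (0.58, SE 0.09). With the B-cell list mean as a covariate the median cytotoxic coefficient for infection was 0.49, with 18 of 24 members above 0. The SE of the mean coefficient over members was 0.21. The members share the same 5 arrays, so this SE does not measure the spread between animals. Just 1 uninfected array reached the B-cell level of the infected arrays. More B-cell-rich lymphoid tissue in the infected samples therefore cannot be told apart from infection. An array batch cannot be told apart either, since the hybridization controls separated the groups. All 27 did so, though they are not independent readings, and no label names a batch. An influx of CD8 T cells into the infected mucosa may underlie the pattern and remains a hypothesis.

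The probe sets lower in the infected animals include the 3 past the threshold. All 6 mitochondrial probe sets were lower in both infected animals than in any uninfected animal, with log2 fold changes from -6.58 to -0.52. Their range was 2.32 even without the lowest (SE of the difference between the extremes 0.23, for extremes picked by their values). This argues against a fall of all mitochondrial RNA by one common factor only if the probe sets respond alike to RNA level. Whether they do was not tested. Less mitochondrial RNA of every kind, by unequal amounts, cannot be told apart from effects on single probe sets, as the 6 were singled out after their values were seen. Where a gene had another tested probe set, it went the same way in 77.8% of 117 lower genes and 80.2% of 131 higher genes (Fisher's exact test, two-sided, p = 0.75), but it was at least 2-fold apart the same way in 13.7% against 35.1% (Fisher's exact test, p = 0.00012). A fall of the whole transcript therefore cannot be told apart from effects on single probe sets, as the share and the size point different ways. Sequence differences between the animals under the probes, such as mitochondrial variants, and the array batch could also act on single probe sets and were not tested. RNA integrity was not tested either. The ratio of 3' to 5' control probe sets of EF1A was 1.45, 1.62 and 3.28 in the uninfected and 1.35 and 1.27 in the infected arrays. The same ratios of actin and GAPDH overlapped between the groups.

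The 5 arrays can be divided into 2 and 3 in 10 ways, too few for a share under 0.05. For probe sets past the adjusted threshold the real division gave 3 and the highest other gave 315, with 2 of the 10 splits reaching the real count, itself included. For probe sets at least 2-fold apart without overlap the counts were 1847 and 2377 (2 of 10), and for gene lists 14 and 14 (2 of 10). Every other division also called lists in camera with the preset correlation. The fewest were 4, for uninfected animal 3 with infected animal 1, and uninfected animal 1 with either infected animal gave 13. A list call in that test is therefore not particular to infection. The highest other division was in each case uninfected animals 2 and 3 against the rest. That points to a structure of the samples in which uninfected animal 1 differs from the other controls. On the first principal component (52.7% of the variance) it scored 14.8, on the side of the infected animals (41.2 and 73.4, against -74.2 and -55.2 in the other uninfected animals). On the second (22.1%) it scored -59.5, away from the infected (54.1 and -6.49) and the other uninfected animals (11.4 and 0.48).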
